A study of Limosilactobacillus reuteri subsp. reuteri F275 with 10 samples.

How the data were processed

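Total RNA from *Limosilactobacillus reuteri* F275, a lactic acid bacterium, was compared on 10 two-colour oligonucleotide arrays in a loop, a layout in which samples are hybridised against each other and not against a common reference. The labels distinguish glucose-type medium (written Glu) from the same with glycerol (Glu&Gly), and exponential (Exp) from early stationary (EarlySta) phase. They number the RNA extracts 1 to 7 and add F1 to F4, taken here as culture numbers. The reading of Glu as glucose and of F as culture is not spelled out in the labels. There were 2 Glu Exp extracts, 2 Glu&Gly Exp extracts, 1 Glu EarlySta extract and 2 Glu&Gly EarlySta extracts. If the extracts of a group did not come from separate cultures, the p-values measure only the spread between extracts.

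The deposited scanner files hold unnormalized spot intensity, per the file headers, as mean and median pixel brightness of the spot and of its local background, from the ImaGene image-analysis program. Channel 1 held Cy3 and channel 2 Cy5 on every array, per the labels. The deposited value table holds log2 ratios of Cy3 over Cy5. Set against the scanner values, each column had a correlation of 1 with the log2 ratio of mean signal minus mean background. The largest difference between them was 0.0064, so scale and direction are known and no centring had been applied. Its column medians for hybridisations A to J were 1.26, -0.05, -0.00, 0.57, 0.16, 0.25, 0.91, 0.20, 0.02 and 0.37. The submitters' processing notes name limma without a version or role. The ImaGene version, the scanner settings and whether control RNA was added are not given in the sources used here.

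Each array had 10807 spots, of which 10263 carried 9308 probes for 1683 gene IDs, with a median of 6 probes per ID. The remaining 544 were control spots. The IDs were looked up in a RefSeq gene table of strain TD1 (assembly ASM43927v1) and 0 matched, so the IDs are given as in the files and no gene names are used. For the same reason the 22 gene lists drawn up in advance could not be tested. The number of extracts, 1 or 2 per group, limits the precision. Between 192 and 322 spots per array carried the poor-quality code 3 and were left out, and 727 to 3491 carried the empty-spot code and were kept.

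Background was corrected by normexp with an offset of 50 on the mean foreground and median background. Log2 ratios of Cy5 over Cy3 were normalized within arrays by loess with a span of 0.3, control spots at weight 0. Spots of a probe were averaged and an ID took the median over its probes. Hybridisations F and J held the same 2 extracts with the dyes swapped and were averaged after turning 1 of them, leaving 9 observations. The relative log2 levels of the 7 extracts were then estimated per ID by least squares, with their sum set to 0. Group means were fitted to these levels with limma 3.58.1 in R 4.3.3, using 3 residual degrees of freedom and an empirical Bayes prior of 3.06 degrees of freedom. Tests were two-sided with Benjamini-Hochberg adjustment over all 1683 IDs, at a threshold of 0.05. The lone Glu EarlySta extract was assumed to vary as the other groups do. An ID's probes spread more in comparisons that used it. Their median SD was 0.30 for glycerol in early stationary phase and 0.35 for growth phase without glycerol. It was 0.13 for glycerol in exponential phase and 0.17 for growth phase with glycerol. The assumption was not tested, and errors that involve this extract may be too small. A spot counted as above background when its signal minus background exceeded the 95th percentile of the 79 negative control spots of its array and channel.

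The comparisons were the glycerol effect in each phase, the growth phase effect with and without glycerol, and the interaction. The rule for named IDs took those past the threshold whose groups did not overlap, with the largest rises and falls. As the IDs have no names, only 2 rises and 2 falls are printed per comparison. Groups cannot overlap or not in the interaction, where the threshold alone was used. Runs of adjacent ID numbers were chosen for description after their values were seen. Correlations between effects were set beside 100 simulations of the loop with no effect, in which IDs varied independently. Runs of at least 4 adjacent ID numbers were set beside 1000 permutations of the ID order, and correlations between adjacent IDs beside 10000.

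The fit was tested on 5 simulated data sets of 1683 IDs, with 100 IDs changed 2-fold and 100 changed 4-fold in the Glu&Gly Exp group. For the glycerol effect in exponential phase it called 80.4% of the 2-fold and 98.6% of the 4-fold changes, and 4.28% of its calls were false. For the interaction it called 14.8% of the 2-fold and 88.8% of the 4-fold changes. The glycerol effect in early stationary phase and the growth phase effect without glycerol held no changed IDs. Recovery was therefore not tested for them. Alternatives covered background, normalization, signal, filters, flags, probe summary, the deposited value table, a dye term, a mixed model, arrays taken as independent, the culture number as a block, the empirical Bayes options and each extract left out. A background-mean setting, a setting without hybridisations A and H and a scaling to control probes were added after the data were seen. Figures were drawn with matplotlib 3.10.9.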

Results

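Transcript levels of *L. reuteri* F275 were measured in exponential and early stationary phase, with and without glycerol, to describe the impact of glycerol on its metabolism. The 7 RNA extracts were compared in a loop of 10 hybridisations. Each extract lay on 2 to 4 arrays. Median gene-spot signal above background ran from 231 to 461 in Cy3 and from 218 to 401 in Cy5. Between 91.8% and 99.2% of gene spots exceeded the negative control level in Cy3, and between 80.6% and 99.2% in Cy5. The lowest shares, 80.6% and 82.3%, belonged to the Glu EarlySta extract in Cy5 on hybridisations A and H. At most 9 gene spots were saturated in a channel. Of the 1683 IDs, 1 in Glu Exp and 1 in Glu EarlySta had no spot above background on any array. A single spot on 1 array was enough to count, so few IDs could fail. The dye-swapped hybridisations F and J had opposite ratios, with r = -0.88 across IDs, which are not independent replicates. Each array's ratios correlated at 0.86 to 0.98 with those predicted from the other arrays.

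Growth phase separated the extracts most. The first principal component held 66.6% of the variance and parted the exponential from the early stationary extracts. The second held 16.8% and parted the Glu EarlySta extract from the Glu&Gly EarlySta pair. Extracts of 1 group differed with an SD over IDs of 0.40 (Glu Exp), 0.52 (Glu&Gly Exp) and 0.48 (Glu&Gly EarlySta) on the log2 scale. Exponential and early stationary extracts differed with SDs of 1.15 to 1.60. Control probes for E1A, an adenoviral sequence that is not part of this bacterium, stood higher in the Glu EarlySta extract than in the Glu Exp extracts, by a median of 1.50 over 7 probes on the log2 scale. All rises and falls below are relative to the bulk of IDs on the array.

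**Figure D1:**
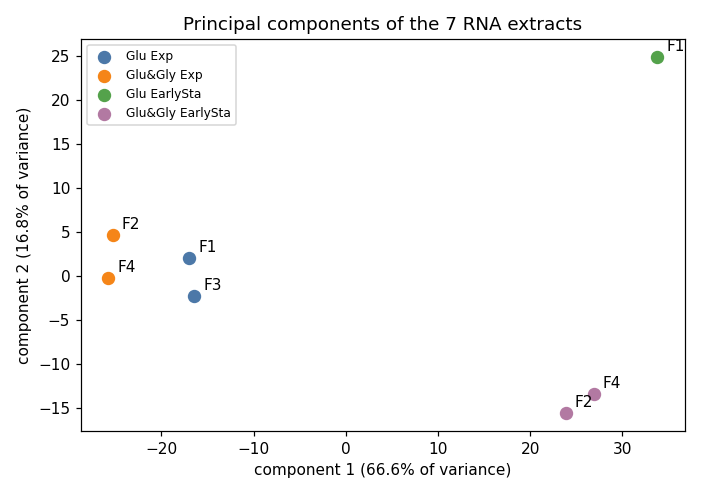
Scores of the 7 RNA extracts on the first and second principal components of their log2 levels over 1683 IDs. Each point is 1 extract, coloured by group and marked with its culture number. The first component, 66.6% of the variance, separates the phases.

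In exponential phase, glycerol went with lower levels of a small set of IDs. LR1RLRE00827 fell by 6.13 ± 0.46 (SE) on the log2 scale, a 70.2-fold difference, with an adjusted p of 0.0032 by limma. Its neighbour by number, LR1RLRE00828, fell by 5.46 ± 0.65 (adjusted p = 0.0069). Both extracts with glycerol lay below both without. The largest rises were smaller, 1.70 ± 0.22 for LR1RLRE00046 (adjusted p = 0.0096) and 1.57 ± 0.25 for LR1RLRE00077 (adjusted p = 0.021). In all, 71 IDs passed the threshold, 64 lower and 7 higher with glycerol, and 68 of them changed at least 2-fold. The probes of LR1RLRE00827 ranged from -6.24 to -5.63, and those of LR1RLRE00046 from 0.72 to 1.96. The count rests on few extracts: it was 25 without Glu Exp F1, 36 without Glu&Gly Exp F2, 41 without Glu Exp F3 and 37 without background correction. LR1RLRE00046 lost its call without Glu Exp F1 or Glu&Gly Exp F2, LR1RLRE00077 under 5 alternatives, and LR1RLRE00828 without background correction, where the rise of LR1RLRE00046 was 0.57. The split was 1 higher and 24 lower without Glu Exp F1 and 14 higher and 50 lower without Glu&Gly Exp F4. Among all IDs with a fitted change of at least 2-fold, called or not, 28 were higher and 75 lower.

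In early stationary phase, glycerol went with changes in both directions. LR1RLRE00092 was higher by 4.51 ± 0.27 (adjusted p = 0.0020, limma), and LR1RLRE00539 by 3.92 ± 0.53 (adjusted p = 0.0068). Of the probes of LR1RLRE00092, only 1 could be fitted on its own. LR1RLRE00555 fell by 4.79 ± 0.61 (adjusted p = 0.0063) and LR1RLRE01448 fell by 4.68 ± 0.24 (adjusted p = 0.0020). The probes of LR1RLRE00539 ranged from 2.33 to 4.96. In all, 391 IDs passed the threshold, 186 higher and 205 lower with glycerol, and 332 changed at least 2-fold. Without background correction the values were 2.48 for LR1RLRE00539 and -2.63 for LR1RLRE00555, and 89 IDs were called higher and 179 lower. The group without glycerol was 1 extract, on which the E1A control probes also stood apart. They did so unequally, by 0.59 to 1.96 over the 7 probes in Glu EarlySta minus Glu Exp. Scaling to them presumes equal control RNA in each extract, and whether any was added is not given. With each extract set to the level of these probes, the median ID moved from 0.03 to 1.14 and 1068 IDs passed, 1020 higher and 48 lower, so the split of rises and falls holds only relative to the bulk of IDs. Without Glu&Gly EarlySta F2 the count was 240.

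The glycerol effects of the 2 phases had little in common across IDs. Their correlation was r = 0.03 (Spearman 0.09), against a mean of 0.05 and a range of -0.07 to 0.15 in 100 simulations with no effect. The simulated IDs varied independently, while adjacent IDs correlate in these data, so that range may be too narrow. The covariance of the glycerol effects was 0.016, against 0.0042 in the simulations. Their correlation was 0.13 without Glu&Gly Exp F2, 0.10 without Glu Exp F3, -0.034 without Glu Exp F1 and -0.037 without Glu&Gly Exp F4. Of the 64 IDs lower with glycerol in exponential phase, 8 were also lower in early stationary phase and 12 were higher. Independent lists would share 7.80 and 7.07.

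**Figure D2:**
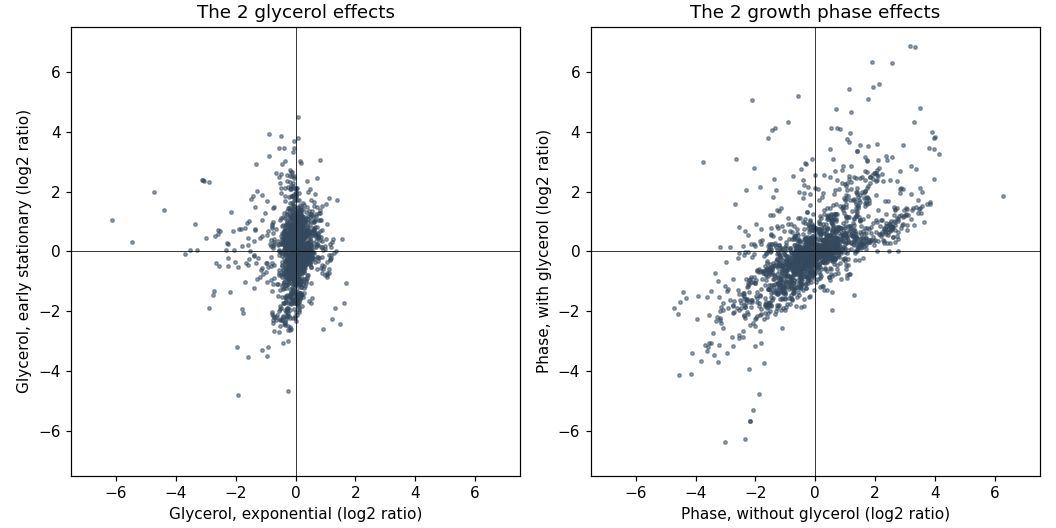
Left, the log2 glycerol effect in early stationary phase against that in exponential phase; right, the log2 growth phase effect with glycerol against that without. Each point is 1 of 1683 IDs. The correlation is 0.03 on the left and 0.65 on the right.

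Between exponential and early stationary phase in cultures with glycerol, the largest rises were those of the adjacent LR1RLRE00788, by 6.88 ± 0.25 (adjusted p = 4.7e-05, limma), and LR1RLRE00789, by 6.85 ± 0.20 (adjusted p = 4.3e-05). The probes of LR1RLRE00788 ranged from 4.77 to 7.80. LR1RLRE01219 fell by 6.38 ± 1.37 (adjusted p = 0.013) and LR1RLRE01218 fell by 6.28 ± 1.46 (adjusted p = 0.017). The wide errors of the last pair come with a large difference between the Glu Exp extracts, and both lost their calls without background correction or without either Glu&Gly EarlySta extract. LR1RLRE01218 also lost its call without Glu&Gly Exp F2. Of the probes of LR1RLRE01218, only 1 could be fitted on its own, at -6.13, and the mean over its probes gave -6.23. In all, 708 IDs passed, 353 higher and 355 lower in early stationary phase, and 514 changed at least 2-fold. Set to the E1A probes, the median ID moved to -0.43, and 517 of 734 calls were lower.

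Without glycerol, LR1RLRE01448 was higher in early stationary phase by 6.29 ± 0.24 (adjusted p = 0.00034, limma) and LR1RLRE01494 by 4.15 ± 0.46 (adjusted p = 0.0013). LR1RLRE01415 fell by 4.74 ± 0.62 (adjusted p = 0.0024) and LR1RLRE01413 fell by 4.60 ± 0.72 (adjusted p = 0.0040). In all, 781 IDs passed, 373 higher and 408 lower, and 646 changed at least 2-fold. A run of 38 adjacent ID numbers, 378 to 415, rose as a block, with a median of 2.55 and a range of 2.15 to 3.49. With glycerol the same run had a median rise of 0.86 and 18 of its IDs passed. Early stationary phase is 1 extract here. The rise of LR1RLRE01494 was 2.43 without background correction and 2.61 set to the E1A probes. Set to the E1A probes, the median ID moved from -0.06 to -1.60, and 1210 of 1284 calls were lower. Without Glu Exp F3 the count was 507, and with the culture number as a fixed replicate block it was 462.

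The growth phase effects with and without glycerol correlated at 0.65 across IDs (Spearman 0.70), against 0.10 in the simulations. Their covariance was 1.22, against 0.0090. In both, 207 IDs rose and 238 fell, where independent lists would share 78.2 and 86.1. Another 23 rose with glycerol and fell without, and 4 fell with glycerol and rose without.

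The interaction asked whether the glycerol effect differed between phases. For LR1RLRE00827 it was higher in early stationary than in exponential phase by 7.18 ± 0.72 (adjusted p = 0.0058, limma), and for LR1RLRE01664 by 6.73 ± 0.51 (adjusted p = 0.0056). It was lower for LR1RLRE01448, at -4.44 ± 0.31 (adjusted p = 0.0056), and for LR1RLRE00046, at -2.77 ± 0.35 (adjusted p = 0.0083). Without background correction the values were 3.08 for LR1RLRE01664, of whose spots 61.1% exceeded background in its weakest group, and -0.85 for LR1RLRE00046. Set to the E1A probes, LR1RLRE00046 was at -1.66. In all, 239 IDs passed, 138 above and 101 below 0, each by at least 2-fold. The count was 77 without Glu Exp F1 (51 above and 26 below 0), 61 without Glu Exp F3 (49 and 12), 85 without Glu&Gly Exp F2 (67 and 18) and 112 without Glu&Gly EarlySta F2 (84 and 28). Without background correction 81 IDs were above and 98 below 0, so which side held more calls depends on that step. It was 365 in a mixed model and 9 with the culture number as a fixed replicate block, in which LR1RLRE01448 and LR1RLRE00046 lost their calls. Set to the E1A probes, the median ID moved to 1.11 and 554 of 560 calls were above 0.

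**Figure D3:**
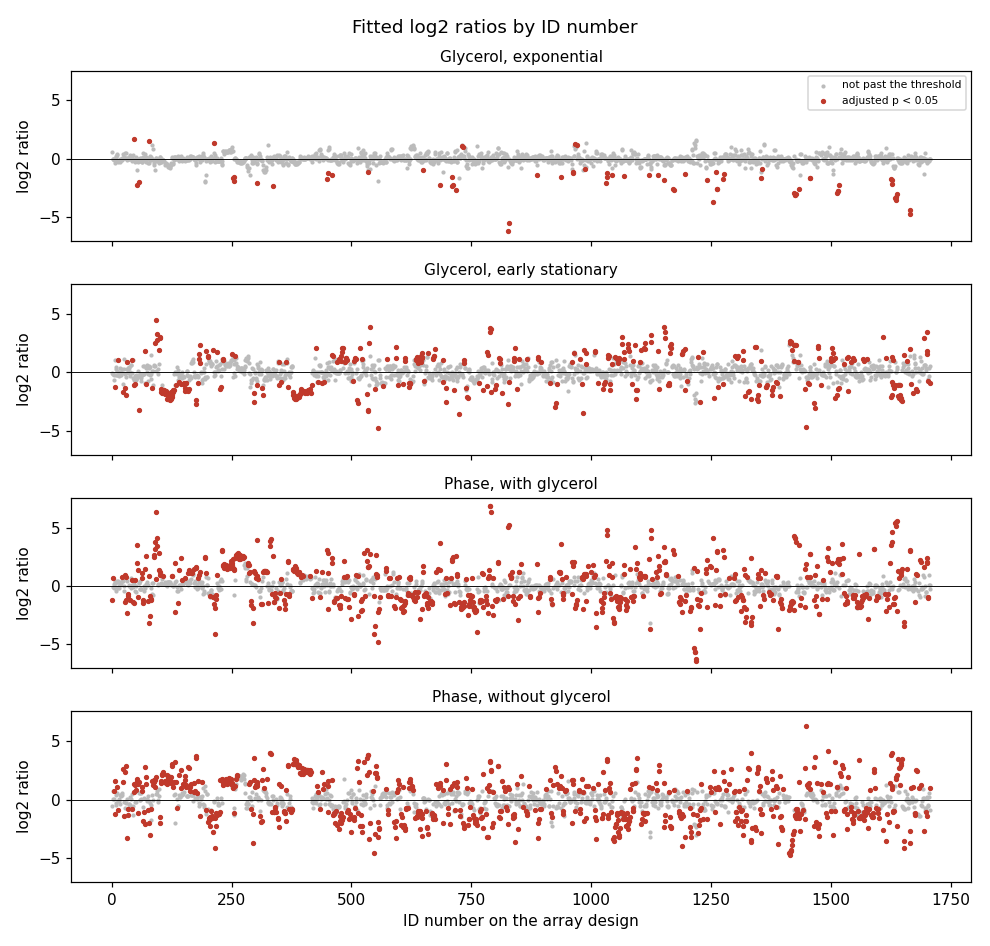
Fitted log2 ratio of each ID against its number on the array design, for the 4 two-group comparisons. Red points passed an adjusted p of 0.05. Blocks of adjacent numbers change together, such as 378 to 415 without glycerol.

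**Figure D4:**
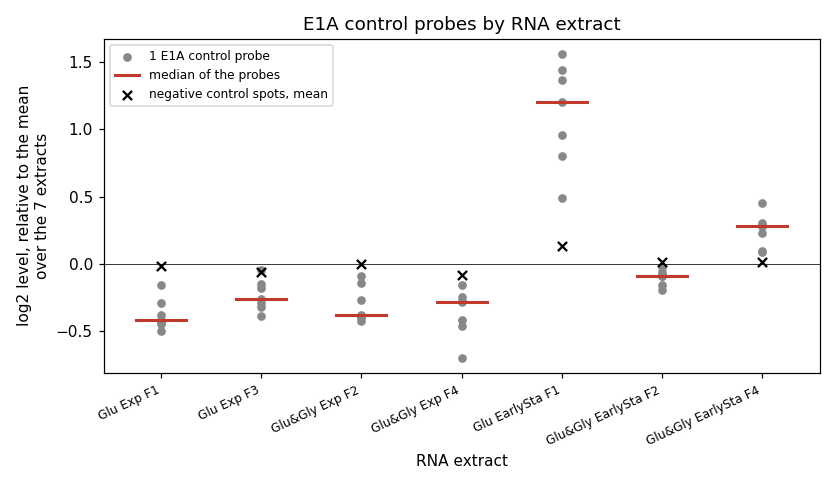
Log2 level of 7 E1A control probes in each RNA extract, relative to the mean over the 7 extracts, with the median as a bar and the mean of the negative control spots as a cross. The Glu EarlySta extract stands highest, at a median of 1.20.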

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

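The tests of the E1A control probes were chosen after their values were seen, and the bound on gene signal and its background estimate were changed after a first comparison had counted a near tie as a difference.

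The glycerol effect differed between growth phases, by a test of the interaction, for 239 IDs. All of these rest on the single Glu EarlySta extract. The count was 77, 61, 85 and 112 without Glu Exp F1, Glu Exp F3, Glu&Gly Exp F2 and Glu&Gly EarlySta F2, and 9 with the culture number as a fixed replicate block. The difference, early stationary minus exponential, was 7.18 on the log2 scale for LR1RLRE00827, 6.73 for LR1RLRE01664, -4.44 for LR1RLRE01448 and -2.77 for LR1RLRE00046. Without background correction LR1RLRE01664 was at 3.08 and LR1RLRE00046 at -0.85. LR1RLRE00827 fell with glycerol in exponential phase. LR1RLRE01448 stood at 5.00 in the single Glu EarlySta extract and between -1.58 and 0.44 in the other 6, so its value rests on that extract.

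The E1A control probes, which no comparison used, carried a signal that stood apart in 1 extract, that of Glu EarlySta. Over the 7 probes brighter than the negative controls, Glu EarlySta exceeded Glu Exp by a median of 1.50 on the log2 scale. Glu&Gly EarlySta exceeded Glu&Gly Exp by 0.39, with extracts that differed, at median levels of -0.09 in F2 and 0.28 in F4. A dye effect is argued against by hybridisation B, which held the extract in Cy3. The mean log2 ratio of Cy5 over Cy3 there was -0.92 ± 0.12 (SE over the probes). This SE comes from 1 array and does not measure the spread between arrays. Residual background in dim spots is argued against by the brightest probe, at 1.96, where the negative control spots differed by 0.17. A smaller share of labelled cDNA from the genes of that extract may lie behind the pattern, but this stays open. The bound was the SD of the Cy5 over Cy3 gene signal (log2) over 7 other arrays, 0.33 with background medians and 0.37 with means. The average imbalance between the dyes was not subtracted. Over the fit's background median, gene signal of the extract lay below the partner's by more than this bound on 1 of 3 arrays, A. Over the background mean this held on 2, A and H, so the count depends on the background estimate. Scan settings, and whether control RNA was added, are not given, and with 1 extract a biological difference was not tested.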

How the results depend on the processing

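The settings using background means, leaving out hybridisations A and H, and scaling to the E1A probes were chosen after the data were seen; the rest were fixed before the data were examined. The named IDs were picked as the largest changes among calls on these same arrays. Their agreement under other settings therefore does not speak for the other calls. Across alternatives, no named ID reversed: 436 of 453 values stayed past the threshold in the same direction and 17 did not, with adjusted p up to 0.11. In size, 8 of these values moved by over 1.5 times on the log2 scale, all towards 0, 6 without background correction and 2 with scaling to the E1A probes. Counts within 1.5 times the values reported came from 14 of 16 alternatives for glycerol in exponential phase, 14 of 16 in early stationary phase, 16 of 17 for growth phase with glycerol, 15 of 17 without it and 12 of 16 for the interaction, leaving out the settings that drop an extract. Neither tally counts Aquantile.

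With 10 arrays taken as independent the counts were 305 for glycerol in exponential phase, 888 in early stationary phase, 1094 for growth phase with glycerol and 906 for the interaction; shared extracts make these too high. Without background correction glycerol in exponential phase gave 37, 35 of them shared. A mixed model gave 365 for the interaction. Scaling to the E1A probes gave 1068 for glycerol in early stationary phase, 1284 for growth phase without glycerol and 560 for the interaction, since it shifts all IDs of an extract alike. The E1A scaling presumes equal control RNA in each extract, which is not known. Aquantile leaves the ratios as they are, so it tests nothing. For the others the cause was not tested.

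Leaving out 1 extract gave 25 to 65 calls for glycerol in exponential phase, 240 to 391 in early stationary phase, 523 to 688 for growth phase with glycerol, 507 to 808 without it and 61 to 231 for the interaction, with fewer extracts in the fit. The correlation of the glycerol effects ran from -0.037 to 0.13. Comparisons that need Glu EarlySta had no value without it.

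The culture numbers share a label between phases. Deviations of F2 from F4 correlated at 0.11 between phases across IDs, from too few pairs to show pairing. As a fixed replicate block, which leaves 1 residual degree of freedom, the culture number gave 462 calls for growth phase without glycerol and 9 for the interaction. As a random block it changed no count by over 1.5 times. The slide as a block was not run, as the files give no slide, and the gene lists were not run, as the IDs have no names. Depth limits dim spots: 80.6% of spots exceeded the negative controls in the weakest channel.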

Other observations

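The test of spot distance and that of left-out hybridisations were set before their results were seen. The test by distance between ID numbers was chosen after.

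Changes came in blocks of adjacent ID numbers. Growth phase without glycerol gave 47 runs of at least 4 calls in the same direction, 16 of rises and 31 of falls, holding 321 IDs, where 1000 permutations of the ID order held at most 80. With glycerol there were 46 runs with 274 IDs. The longest run, numbers 378 to 415, was lower with glycerol in early stationary phase, with a median of -1.72 and 34 of 38 IDs past the threshold, and had a median of 0.01 in exponential phase with 0 past it. The 10 adjacent numbers, 1413 to 1422, fell without glycerol, with a median of -4.12. The growth phase effect without glycerol and the early stationary glycerol effect share the single Glu EarlySta extract. Across IDs they correlated at -0.60, against a mean of -0.63 in the simulations with no effect. Their covariance was -0.83, against -0.068 in the simulations, so the effects were larger than simulated. As the extract is shared, the fall of numbers 378 to 415 with glycerol is not separate evidence from their rise without it.

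Adjacent IDs correlated at 0.54 in the growth phase effect without glycerol, with a permutation p of 0.0001, the smallest that 10000 permutations can give. Differences between replicate extracts of 1 group had a like correlation, 0.52 in Glu Exp, 0.58 in Glu&Gly Exp and 0.50 in Glu&Gly EarlySta, so it is not particular to growth phase or glycerol. Spots lying close together on the array are argued against as the cause: over 439 adjacent pairs with no spots within 10 rows and columns of each other the correlation was 0.52. At a distance of 50 numbers it was -0.017. If the numbers follow the chromosome, which the files do not state, this is consistent with genes of shared transcripts or neighbourhoods changing together.

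Replicate extracts also differed in a block. Over numbers 1215 to 1219, Glu Exp F1 exceeded Glu Exp F3 by 3.47 to 5.04 on the log2 scale, and 0 other IDs differed 8-fold between this pair. The median levels were 3.53 in Glu Exp F1, -0.98 in Glu Exp F3, 3.53 in Glu&Gly Exp F2 and 1.55 in Glu&Gly Exp F4. A single deviant hybridisation is argued against, as the smallest median difference with any 1 left out was 3.86. That value, without A, covers 3 of the 5 IDs, since the spots of the others were left out on D. With D, E, F or J left out, the median over all 5 was 4.45 to 5.04. A difference between the cultures, such as the moment of sampling, may account for it and was not tested.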
